A study of Mus musculus with 6 samples.

How the data were processed

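Retinae of newborn Meg2 (Ptpn9) knockout and wild-type mice on a C57BL/6NTac background were profiled on Affymetrix Mouse Gene 1.0 ST arrays. Per the labels' protocols, pups were genotyped, tissue was snap frozen, both retinae of an animal were pooled, and total RNA was column purified with a DNase step. Random-primed RNA was amplified and turned into biotin-labelled sense-strand cDNA for hybridisation. The labels call the samples of each genotype biological replicates, 3 per group, and each number from 1 to 3 appears in both groups.

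The deposited values are log2 signals per transcript cluster. Per the submitters' processing notes they were made with Affymetrix Expression Console and RMA, and Transcriptome Analysis Console was also used. RMA corrects the background, sets all arrays to 1 distribution of probe values and summarises probes on the log2 scale, so a shift shared by most transcripts would be removed. Software versions, annotation release and the authors' statistical test are not given in the sources used here. The values bear out a log2 scale, with array medians from 7.84 to 7.91. No scan date or slide is given in the sources used here, so no technical batch beyond the replicate number could be tested.

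The table held 35557 clusters. A platform annotation named exactly 1 gene for 21789, several for 1621 and none for 12147, which are unnamed here and not without a gene. Entrez identifiers of 21698 of the single-gene clusters matched the gene table of assembly GRCm38.p6, which changed 0 symbols. That table was used only for names and for the order of genes along chromosomes. The 23410 clusters with at least 1 gene were tested and no filter on dim signal was applied. The unnamed clusters held 0 at an adjusted p under 0.05 and 770 at an unadjusted p under 0.05 in limma with every cluster in the fit. Genes that share 1 cluster, some globins among them, were not separated and were not counted as list members.

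Knockout was compared with wild type by limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the log2 values as deposited, with Benjamini-Hochberg adjustment over the tested clusters and a threshold of 0.05. A difference is knockout minus wild type, and its SE is the moderated one. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1, so single genes were not tested that way. Tables were handled with pandas 2.3.3 in Python 3.11.15, and figures drawn with matplotlib 3.10.9.

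Before the data were examined, 37 gene lists, the tests, the alternatives and the rule for named genes were fixed. Each list gene stood in as its single-gene cluster with the highest mean signal, and lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over lists. Camera compares a list with all other genes. It was repeated with a correlation estimated per list, and fry was run for movement one way or either way. Members were also adjusted over the list alone. Named genes were Ptpn9 and, as no gene passed correction, the 8 largest differences in each direction among single-gene clusters with an unadjusted p under 0.05, arrays that did not overlap and a mean above the median signal. Of these, 1 gene with higher signal in the knockout is not reported here. In each list, up to 4 members that passed over the list alone were selected, or otherwise the 2 with the highest signal, and not all of the latter are given below. Other list members, such as Cdh5, Emcn, Flt1, Klf15, Timp3, Mvk, Fdps, Ccnb2, Sdhb and Asns, were chosen after their values were seen, as were genes that passed only with the replicate block and the neighbours of Ptpn9 named singly.

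The replicate numbers come from the sample labels, which do not say what they mark. The sample titles also carry a running code, whose meaning is not given in the sources used here. In it the knockout sample of each number comes directly before the wild-type sample of that number. Order within a pair therefore follows genotype, and an effect of that order cannot be told apart from genotype. Deviations from the group means correlated between arrays of the same number, at 0.476, 0.485 and 0.455 for replicates 1, 2 and 3, all above the 0.1 taken as pairing, so the fit with the number as a block was computed for every result. Arrays of the same number also shared their Xist and Y-linked pattern. Across all pairs of arrays Pearson's r over clusters lay between 0.997 and 0.998, with no identical arrays.

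For the neighbourhood of Ptpn9, the 25 named and measured genes on each side were compared with all others by Fisher's exact test, two-sided. Alternatives were median centring, cyclic loess, a variance trend, robust variance, array weights, filters at the 25th percentile and the median of signal, every row of the table, the replicate block, a sex score and a lens score as covariates, and each array left out. A fit without replicate 2 of both groups was added after seeing the data, as were all alternatives for the neighbourhood of Ptpn9. The sex score is the mean Y-linked minus Xist signal and the lens score the mean signal of the lens list. The steps were tested on simulated data drawn at the size of this series, in 10 runs over 23410 clusters. There, a list of 25 genes shifted by 0.15 was called in 10 of 10 runs, and 2 of 360 unshifted lists were called, with genes simulated as independent.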

Results

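Gene expression was measured in retinae dissected from newborn mice (postnatal day 0) that lacked Meg2 and from wild-type controls. Meg2 is the protein tyrosine phosphatase encoded by Ptpn9, which carries an amino-terminal CRAL-TRIO (SEC14 homology) lipid-binding domain and is known as a regulator of secretory vesicle fusion and of receptor signalling. The series held 3 knockout and 3 wild-type samples on whole-transcript arrays, and per the labels each array carried RNA from the pooled retinae of 1 animal, although both replicate 2 arrays carried Xist and Y-linked signal together. Values were normalised log2 signals of transcript clusters, the probe groups that each cover a transcript. The median log2 signal per array lay between 7.84 and 7.91, and the number of arrays, 3 per genotype, limited the precision of every comparison.

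The first question was whether the Ptpn9 transcript was lower in the samples labelled as knockout. Ptpn9 signal was lower on each of the 3 knockout arrays than on any wild-type array. The knockout arrays read 9.31, 9.58 and 9.28 on the log2 scale (mean 9.39 ± 0.16, SD, n = 3) and the wild-type arrays 10.05, 9.93 and 9.94 (9.97 ± 0.067, SD, n = 3). The difference was -0.58 (SE 0.087), so knockout signal was 0.67 of wild type. As a comparison fixed in advance for this gene alone, its unadjusted p was 0.000108 (limma). It did not pass correction over the 23410 named clusters (limma, adjusted p = 0.437). Ptpn9 was read by 1 cluster spanning the transcript, and the deleted part of the gene is not given in the sources used here, so probes outside it do not test the deletion.

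**Figure D1:**
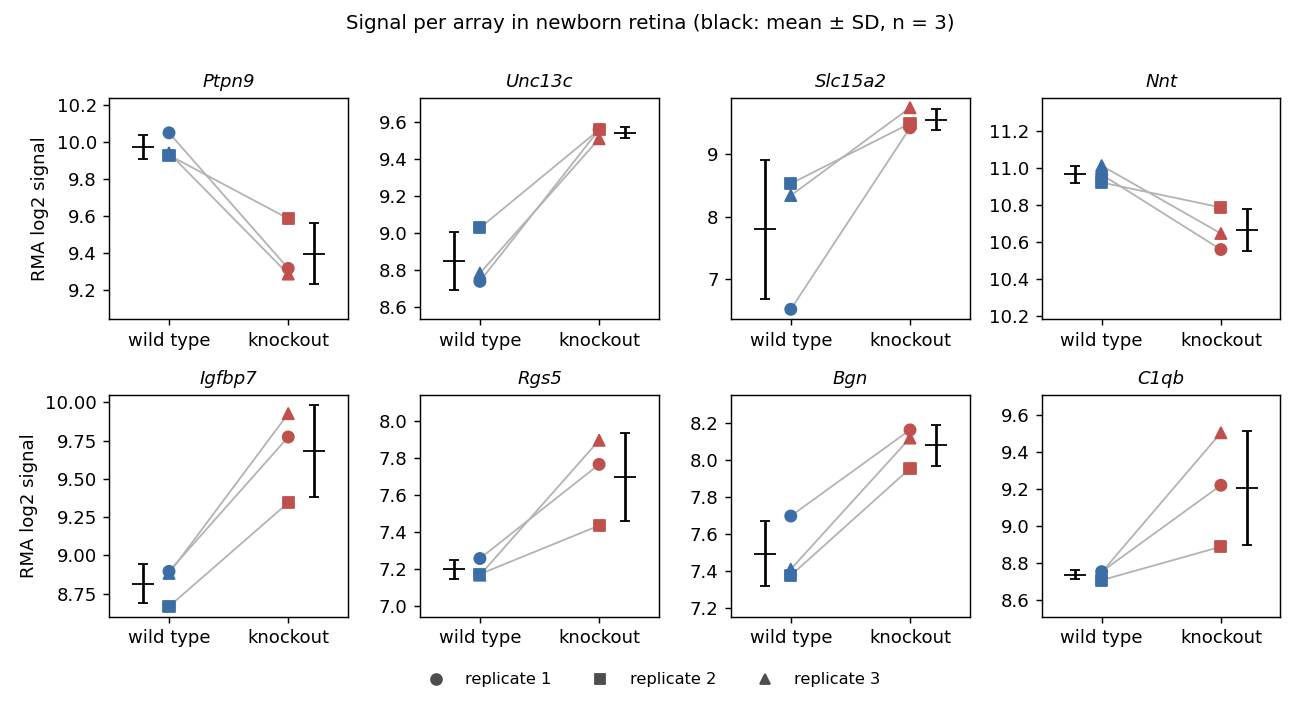
Normalised log2 signal (vertical axes) of 8 genes on each array, with wild-type arrays in blue and knockout arrays in red. Lines join arrays with the same replicate number and black bars show the mean ± SD (n = 3); Ptpn9 lay between 9.28 and 9.58 in the knockout and between 9.93 and 10.05 in the wild type, and the wild-type Slc15a2 values included 1 array at 6.51.

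The second question was which transcripts differed between knockout and wild-type retina. Unc13c, which encodes the vesicle priming protein Munc13-3, was higher in the knockout in 7 of 7 clusters, by 0.30 to 0.83 on the log2 scale, and in each of them the lowest knockout array lay above the highest wild-type array. The brightest Unc13c cluster read 9.54 ± 0.029 in the knockout and 8.85 ± 0.16 in the wild type (SD, n = 3), a 1.62-fold difference (log2 0.69, SE 0.081; limma, adjusted p = 0.179). The Unc13c cluster with the largest difference (0.83) had an adjusted p of 0.0138 in limma with the replicate number as a block and of 0.437 without it. It was the 1 cluster of 23410 past an adjusted p of 0.05 in the blocked fit, and without the block 0 clusters passed. This cluster was the dimmest of the 7, with a mean of 6.32 against a median of 8.51 over tested clusters. Its SE was 0.125 without the block and 0.045 with it.

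Igfbp7, a secreted insulin-like growth factor binding protein abundant in endothelium, was 1.82-fold higher in the knockout (log2 0.87, SE 0.14; limma, adjusted p = 0.449). Among the genes selected for naming, the largest difference belonged to Slc15a2, a proton-coupled peptide transporter, at 1.76 (SE 0.44), with wild-type arrays at 6.51, 8.53 and 8.34. Without the wild-type replicate 1 array the Slc15a2 difference was 1.12. Hif3a, an alpha subunit of the hypoxia-inducible factors, differed by 0.90 (SE 0.31), and its knockout arrays read 9.36, 9.46 and 10.75. Without the knockout replicate 3 array the Hif3a difference was 0.45. C1qb, a chain of complement C1q, differed by 0.47 (SE 0.13), Abca1, a cholesterol and phospholipid efflux transporter, by 0.46 (SE 0.12), and Crhbp, which binds corticotropin-releasing hormone, by 0.45 (SE 0.12). None of these genes passed correction.

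Among the genes selected for naming with lower signal in the knockout, which lay above the median signal, Ptpn9 showed the largest difference. Mns1, a protein of motile cilia and flagella, differed by -0.37 (SE 0.093) and Adpgk, an ADP-dependent glucokinase, by -0.37 (SE 0.10). The microtubule-associated protein gene Map1a differed by -0.32 (SE 0.099), the DNA helicase gene Ddx11 by -0.32 (SE 0.089) and the linker histone gene H1f2 by -0.30 (SE 0.085). The mitochondrial genes Nnt, which encodes nicotinamide nucleotide transhydrogenase, and Rtn4ip1 differed by -0.30 (SE 0.071) and -0.28 (SE 0.094). Arrays of knockout and wild type did not overlap in these genes because the rule for naming required it, and none of the genes passed correction.

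Over all named clusters, limma gave 395 higher and 408 lower in the knockout at an unadjusted p under 0.05, which is 3.43% of those tested, and the lowest adjusted p was 0.0781. With the replicate number as a block, 1043 were higher and 1020 lower at that unadjusted level. Knockout and wild-type arrays did not overlap in 1973 clusters, or 8.43%, where chance gives 10% if arrays are exchangeable, which the pairing of replicate numbers does not grant. Unchanged clusters simulated with such pairing did not overlap in 4.97%, and had an unadjusted p under 0.05 in 2.04% without the block and 5.7% with it. The simulated replicate effects were set larger than those estimated from the arrays, which lowers the 4.97% and the 2.04%. Setting the observed shares beside them therefore does not show an excess of changed clusters. In these simulated data, limma without the block recovered 7.76% of clusters changed by 0.3, 61.6% of those changed by 0.6 and 89.1% of those changed by 1 on the log2 scale. Over the 10 runs 670, 670 and 660 clusters were changed by these sizes. Recovery after adjustment depends on how many clusters change and on the replicate effects. These shares are therefore not the power to find a change in this series.

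The third question was whether sets of genes shifted together, and 37 lists of retinal cell types, pathways and other tissues were tested with limma's camera. On average, genes of endothelial cells and pericytes, FOXO and insulin signalling genes and ribosomal protein genes lay higher in the knockout. Cholesterol synthesis and mitosis genes lay lower on average. Of these lists, only the mitosis list had per-array means that did not overlap between knockout and wild type. Within each replicate number every one of these lists differed in its stated direction. With the preset correlation of 0.01, 10 lists lay higher and 4 lower at an adjusted p under 0.05, and with the correlation estimated from the 6 arrays 0 of the 37 passed, with a lowest adjusted p of 0.576. The mean differences were small, from -0.11 to 0.15 on the log2 scale. The tests of one-way and of mixed movement in fry also called 0 lists, with lowest adjusted p of 0.511 and 0.12. No list member passed correction over all clusters.

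The endothelial and pericyte list had 25 of 27 measured members above 0, with a mean difference of 0.15 (camera, adjusted p = 2.23e-09, and adjusted p = 0.576 with an estimated correlation). Adjusted over the list alone, 1 member passed, the pericyte gene Rgs5 (log2 0.50, SE 0.11; limma, adjusted p = 0.0363). With the replicate block 4 members passed over the list alone, as Cdh5, the gene of VE-cadherin (log2 0.54, adjusted p = 0.0463), Mmrn2 (0.23, adjusted p = 0.0258) and Robo4 (0.19, adjusted p = 0.0426) joined Rgs5 in limma. The endothelial surface gene Emcn differed by 0.50 (SE 0.14) and the vascular endothelial growth factor receptor gene Flt1 by 0.35 (SE 0.14). Without knockout replicate 3 the Flt1 difference was 0.18, and without knockout replicate 1 that of Mmrn2 was 0.14. Per array, the list's mean stood at 0.14, -0.047 and 0.14 in the knockout and at -0.023, -0.11 and -0.099 in the wild type relative to all 6 arrays, higher in the knockout for 3 of 3 replicate numbers. The mean signal of the lens list, a marker of tissue outside the retina, was also higher in the knockout, by 0.13. With that lens signal as a covariate the vascular difference was 0.048 (camera, adjusted p = 0.13), and among clusters above the median signal its 6 members averaged 0.028 (camera, adjusted p = 0.429).

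Several other lists of tissue around or within the retina lay higher beside the lens signal. The lens list itself had 22 of 25 members above 0, with a mean of 0.13 and a median of 0.047 (camera, adjusted p = 0.00323, and adjusted p = 0.644 with an estimated correlation). Its members with the highest signal, the beta crystallin gene Crybb1 and the connexin gene Gja3, differed by 0.14 (SE 0.084) and -0.0075 (SE 0.074). Microglia and immune genes had 16 of 22 members above 0 (camera, adjusted p = 0.00507, and adjusted p = 0.717 with an estimated correlation). Its complement genes C1qa, C1qb and C1qc passed over the list alone with the replicate block (limma, adjusted p = 0.0368 for each) and not without it, while Laptm5 differed by 0.15 (SE 0.088), or by 0.24 without knockout replicate 2 and 0.10 without knockout replicate 3 or wild-type replicate 2. Periocular mesenchyme genes had 13 of 18 above 0 (camera, adjusted p = 0.0139, and adjusted p = 0.644 with an estimated correlation), and the proteoglycan gene Bgn passed over the list alone (log2 0.59, SE 0.097; limma, adjusted p = 0.00381). Corneal and ciliary epithelial genes had 14 of 19 above 0 (camera, adjusted p = 0.0318, and adjusted p = 0.576 with an estimated correlation), with Mab21l2 at -0.0087 (SE 0.066) and Wfdc1 past the list-alone correction only in the blocked fit (log2 0.34; limma, adjusted p = 0.00934). Without knockout replicate 1 these camera calls were lost for lens (adjusted p = 0.195), immune (0.422), mesenchyme (0.651) and corneal genes (0.338). Without wild-type replicate 3 they were lost for lens (0.0531), mesenchyme (0.273) and corneal genes (0.135), without wild-type replicate 2 for lens (0.0703) and immune genes (0.142), and without knockout replicate 3 for immune genes (0.0578). With the lens covariate the calls were lost for immune (adjusted p = 0.999), mesenchyme (0.339) and corneal genes (0.184) in camera. In that order the means were -0.0079, 0.042 and 0.054 with the covariate and 0.095, 0.075 and 0.057 without it. The corneal mean thus kept its size. Array weights ended the mesenchyme (0.0543) and corneal calls (0.073), the median filter on signal ended both (0.482 and 0.482), and all clusters in the fit ended the corneal call (0.0544). The filter at the 25th percentile ended the lens (0.0538) and corneal calls (0.0977). The mesenchyme mean of 0.075 was 0.037 without knockout replicate 1. Without knockout replicate 3 the lens mean was 0.071 (camera, adjusted p = 0.00432).

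FOXO targets and insulin signalling genes had 20 of 21 members above 0, with a mean of 0.11 (camera, adjusted p = 8.35e-06, and adjusted p = 0.576 with an estimated correlation). Cdkn1b, a cell cycle inhibitor, differed by 0.10 (SE 0.079), the kinase gene Akt1 by 0.052 (SE 0.056) and the transcription factor gene Klf15 by 0.22 (SE 0.076), or 0.15 without knockout replicate 3. Ribosomal protein genes had 20 of 22 above 0, with a mean of 0.066 (camera, adjusted p = 0.000433, and adjusted p = 0.644 with an estimated correlation), and Rplp0 and Rps6 differed by 0.047 (SE 0.066) and 0.051 (SE 0.060). Genes of Muller glia and astrocytes had 16 of 20 above 0, with a mean of 0.066 (camera, adjusted p = 0.00323, and adjusted p = 0.576 with an estimated correlation). Within that list the fatty acid binding protein gene Fabp7 differed by 0.15 (SE 0.061), the intermediate filament gene Vim by 0.039 (SE 0.056) and the protease inhibitor gene Timp3 by 0.20 (SE 0.065). None of the members of these lists passed over the list alone. Without knockout replicate 3 the ribosomal mean was 0.042 (camera, adjusted p = 0.0436). With the lens signal as a covariate the glial call was lost (camera, adjusted p = 0.382).

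Hypoxia and glycolysis genes had 20 of 24 members above 0, with a mean of 0.088 (camera, adjusted p = 0.00507, and adjusted p = 0.717 with an estimated correlation). Slc2a1, the glucose transporter gene, differed by 0.080 (SE 0.072) and the lactate dehydrogenase gene Ldha by -0.0057 (SE 0.060). Without knockout replicate 3 the hypoxia mean was -0.0033 (camera, adjusted p = 0.873). Interferon response genes had 12 of 18 above 0, with a mean of 0.049 (camera, adjusted p = 0.0447, and adjusted p = 0.644 with an estimated correlation), and the replicate block ended this call (camera, adjusted p = 0.0742). B2m, the light chain of class I histocompatibility molecules, differed by 0.12 (SE 0.065) and Stat2 by -0.075 (SE 0.085). Leaving out knockout replicate 1, wild-type replicate 1 or wild-type replicate 3 ended the interferon call as well (camera, adjusted p = 0.651, 0.0703 and 0.196), and without knockout replicate 1 its mean was 0.020. The lens covariate, array weights, cyclic loess, the variance trend, all clusters in the fit and the filter at the 25th percentile of signal ended it too (camera, adjusted p = 0.246, 0.12, 0.0882, 0.066, 0.0679 and 0.0538). In that order the interferon means were 0.047, 0.042, 0.044, 0.049, 0.049 and 0.059, near the main value of 0.049. With the lens covariate the hypoxia mean was -0.055 (camera, adjusted p = 0.456).

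Cholesterol synthesis genes had 15 of 16 members below 0, with a mean of -0.11 (camera, adjusted p = 5.77e-06, and adjusted p = 0.644 with an estimated correlation). Mevalonate kinase (Mvk) differed by -0.21 (SE 0.058), farnesyl diphosphate synthase (Fdps) by -0.17 (SE 0.068) and the pathway's transcription factor gene Srebf2 by -0.058 (SE 0.058), and no member passed over the list alone. Proliferation and mitosis genes had 24 of 26 below 0, with a mean of -0.064 (camera, adjusted p = 3.98e-05, and adjusted p = 0.576 with an estimated correlation). The replication clamp gene Pcna differed by -0.049 (SE 0.074) and the cyclin genes Ccna2 and Ccnb2 by -0.019 (SE 0.054) and -0.14 (SE 0.060). With the lens signal as a covariate the mitosis call was lost (camera, adjusted p = 0.259) and the cholesterol call was not (camera, adjusted p = 0.000247). Without wild-type replicate 3 the cholesterol mean was -0.057 (camera, adjusted p = 0.0258).

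Nuclear-encoded respiratory chain genes had 23 of 29 members below 0, with a mean of -0.048 (camera, adjusted p = 0.00507, and adjusted p = 0.717 with an estimated correlation). Within it Atp5b and Cox6c differed by 0.0046 (SE 0.054) and -0.027 (SE 0.061), and the succinate dehydrogenase gene Sdhb by -0.17 (SE 0.061). Unfolded protein and integrated stress response genes had 16 of 22 below 0, with a mean of -0.046 (camera, adjusted p = 0.0345, and adjusted p = 0.717 with an estimated correlation). The endoplasmic reticulum chaperone genes Hsp90b1 and Calr differed by -0.052 (SE 0.072) and -0.090 (SE 0.057), and asparagine synthetase (Asns) by -0.21 (SE 0.088). Both calls were lost without knockout replicate 1 (camera, adjusted p = 0.651 and 0.743) and without wild-type replicate 3 (camera, adjusted p = 0.135 and 0.646), and with the lens signal as a covariate (camera, adjusted p = 0.511 and 0.339). With the lens covariate the stress response mean kept its size, at -0.046, and the respiratory chain mean was -0.031. Without knockout replicate 1 the respiratory chain mean was -0.016 and the stress response mean -0.021. The stress response call was also lost with array weights (camera, adjusted p = 0.12) and with all clusters in the fit (0.0643).

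**Figure D2:**
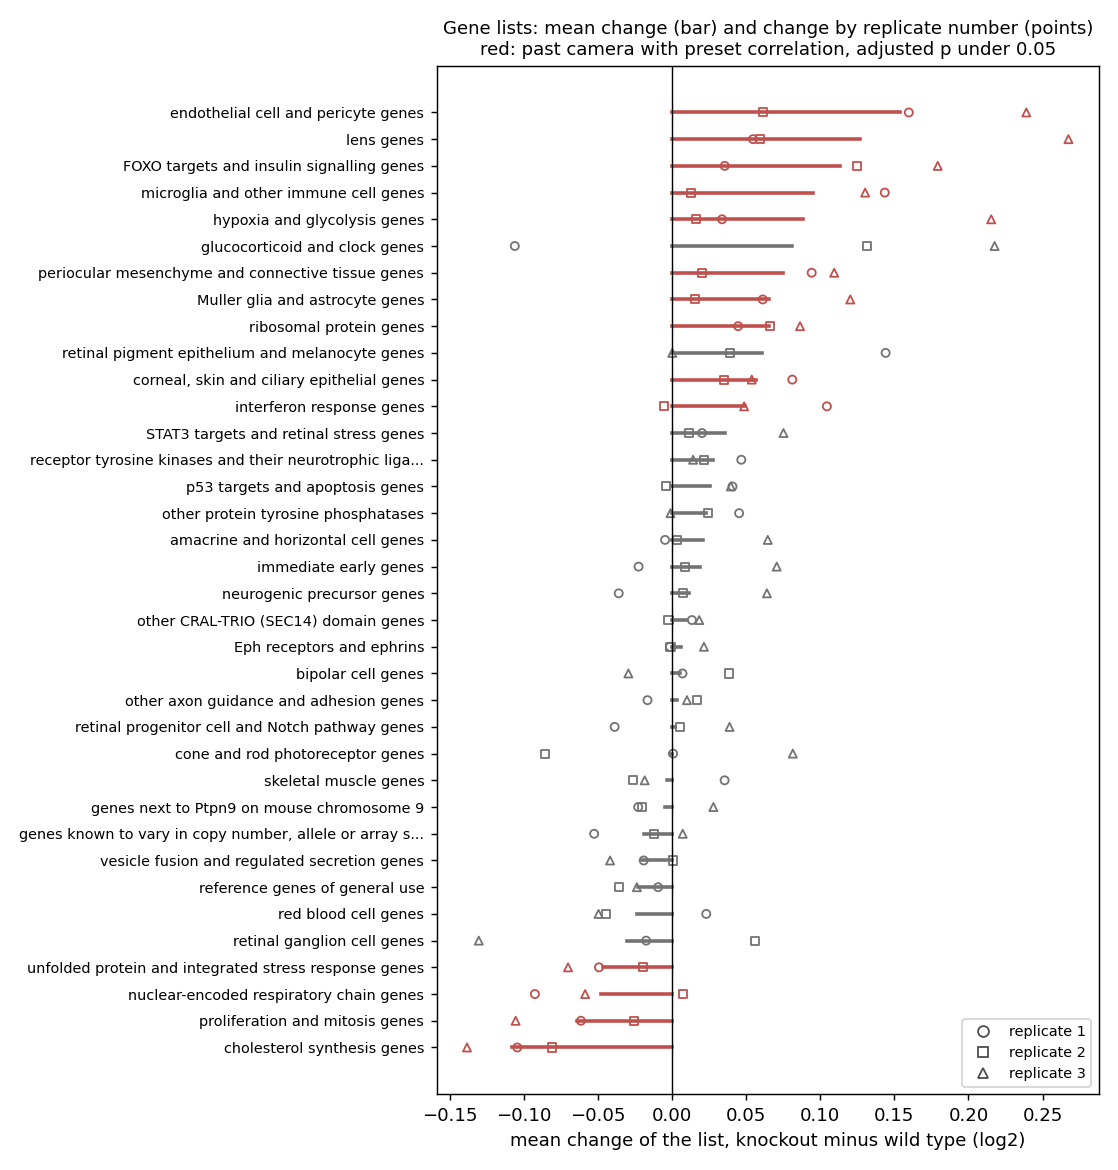
Mean difference of each gene list except the Xist and Y-linked list, which is not drawn (horizontal axis, log2, knockout minus wild type), as a bar. Points show the difference within each replicate number. Red lists passed camera with the preset correlation at an adjusted p under 0.05; the endothelial and pericyte list has the highest mean (0.15) and the cholesterol synthesis list the lowest (-0.11).

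No list of retinal progenitors or neurons passed camera. Retinal progenitor genes averaged 0.0019 (camera, adjusted p = 0.918), and their most abundant members, the cyclin gene Ccnd1 and the homeobox gene Lhx2, differed by 0.013 (SE 0.054) and 0.0017 (SE 0.058). Neurogenic precursor genes averaged 0.012 (adjusted p = 0.885), with Otx2 at -0.0012 (SE 0.073). Ganglion cell genes averaged -0.031 (adjusted p = 0.282), with the neurofilament gene Nefl at -0.11 (SE 0.10), amacrine and horizontal cell genes 0.021 (adjusted p = 0.368), with Tfap2b at 0.030 (SE 0.060), and bipolar cell genes 0.0053 (adjusted p = 0.918), with Prkca at -0.069 (SE 0.066). Photoreceptor genes averaged -0.0013 (adjusted p = 0.918), with the S-cone opsin gene Opn1sw at 0.055 (SE 0.10). The ganglion and photoreceptor results depended on single arrays and on the lens covariate, since without knockout replicate 2 both lists passed, at -0.089 (adjusted p = 8.43e-05) and 0.082 (adjusted p = 0.0246). Ganglion cell genes also passed without wild-type replicate 1 (mean -0.060, adjusted p = 0.0226), and photoreceptor genes without knockout replicate 3, with the opposite sign (mean -0.092, adjusted p = 0.00531). With the lens signal as a covariate both passed, ganglion cell genes at 0.079 (adjusted p = 0.00447) and photoreceptor genes at -0.16 (adjusted p = 0.000247). Without replicate 2 of both groups ganglion cell genes passed at -0.074 (adjusted p = 0.000927).

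Of the lists chosen for known roles of Meg2, the FOXO and insulin genes above passed camera with the preset correlation only (adjusted p = 0.576 with an estimated correlation), and those that follow did not pass. Vesicle fusion and secretion genes averaged -0.020 (adjusted p = 0.283), and the SNARE gene Snap25 differed by -0.016 (SE 0.069). Other protein tyrosine phosphatases averaged 0.023 (adjusted p = 0.356), and in the blocked fit 1 of 36 passed over the list alone, the endothelial phosphatase gene Ptprb (log2 0.27; limma, adjusted p = 0.0233). Eph receptors and ephrins averaged 0.0064 (adjusted p = 0.918), other axon guidance genes 0.0035 (adjusted p = 0.957), receptor tyrosine kinases and ligands 0.028 (adjusted p = 0.283), STAT3 targets 0.036 (adjusted p = 0.518) and other CRAL-TRIO domain genes 0.0098 (adjusted p = 0.82). Among further pathway lists that did not pass, p53 targets averaged 0.025 (adjusted p = 0.732), immediate early genes 0.019 (adjusted p = 0.91) and glucocorticoid and clock genes 0.081 (adjusted p = 0.91), and in that last list Hif3a and Per1 passed over the list alone only with the replicate block (limma, adjusted p = 0.0461 for each). Without knockout replicate 1 the glucocorticoid and clock list passed, at 0.19 (camera, adjusted p = 0.00743), while without knockout replicate 2 or 3 its mean was 0.025 or 0.033 (camera, adjusted p = 0.18 and 0.979).

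Among lists of other tissues, pigment epithelium and melanocyte genes averaged 0.061 (camera, adjusted p = 0.0724), red blood cell genes -0.024 (adjusted p = 0.227) and skeletal muscle genes -0.0031 (adjusted p = 0.957). The pigment list passed camera with median centring (adjusted p = 0.0405), with the sex score covariate (0.047), and without knockout replicate 2 (adjusted p = 0.0341), knockout replicate 3 (0.00131) or wild-type replicate 1 (0.00598). Its rise rested on knockout replicate 1, without which the mean was -0.011 (camera, adjusted p = 0.772). Xist and Y-linked genes averaged -0.025 (adjusted p = 0.783), general reference genes -0.023 (adjusted p = 0.633) and a list of 31 neighbours of Ptpn9 -0.0050 (adjusted p = 0.878). Genes known to vary between mouse substrains averaged -0.019 (adjusted p = 0.91), and 2 of 10 passed over the list alone. These were Nnt, which carries a known deletion in C57BL/6J and not in C57BL/6N mice (log2 -0.30; limma, adjusted p = 0.0231), and Alad, a haem synthesis gene (log2 -0.20; limma, adjusted p = 0.0493). Mean, median and camera direction disagreed in sign in the progenitor, photoreceptor, bipolar, Eph, axon guidance, STAT3, glucocorticoid, muscle, substrain and reference lists.

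The last comparison asked whether genes next to Ptpn9 differed more often than genes elsewhere, since a targeted allele can carry a linked chromosome segment. Of the 50 measured genes within 25 places of Ptpn9 on chromosome 9, 8 had an unadjusted p under 0.05 in limma, or 16%, against 3.34% of the other genes (Fisher's exact test, two-sided, p = 0.000245, odds ratio 5.51). Lower in the knockout were Snupn (-0.24) and Gm10658 (-0.34, and -0.58 in a dimmer second cluster) directly beside Ptpn9, the kinase gene Peak1 (-0.24) and the nicotinic receptor gene Chrna3 (-0.17). Higher were the DNA glycosylase gene Neil1 (0.17), the mannosidase gene Man2c1 (0.16), the cytochrome gene Cyp1a2 (0.22) and Ubl7 (0.13). With 1 array left out Snupn moved to -0.16 (wild-type replicate 3), the first Gm10658 cluster to -0.21 (wild-type replicate 1) and Cyp1a2 to 0.12 (wild-type replicate 2). Beside Fisher's exact test, which counts either direction, camera asked whether the 50 genes shifted one way, and its p was 0.0614 without the block and 0.0348, downwards, with it. Unc13c, Mns1 and Adpgk, named above, lay on the same chromosome 169, 157 and 42 genes from Ptpn9. The excess was not past 0.05 without knockout replicate 1 (8%, Fisher's exact p = 0.327), knockout replicate 3 (8%, p = 0.0788), wild-type replicate 1 (6%, p = 0.181) or wild-type replicate 3 (6%, p = 0.15), nor with the lens covariate (8%, p = 0.108).

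**Figure D3:**
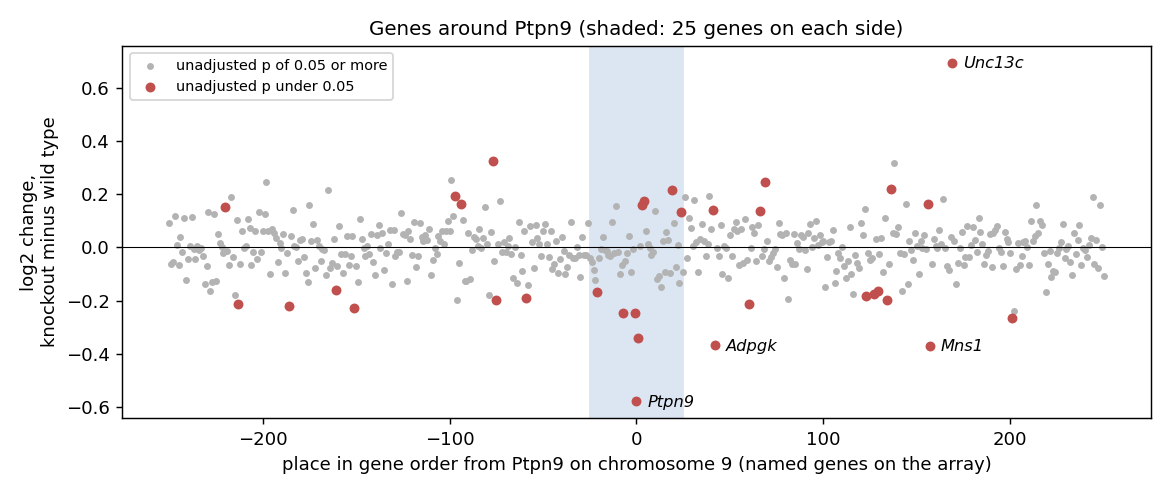
Log2 difference, knockout minus wild type (vertical axis), of measured genes in their order from Ptpn9 on chromosome 9 (horizontal axis, number of genes), with the 25 genes on each side shaded. Red points have an unadjusted p under 0.05; 8 of the 50 shaded neighbours are red, and Unc13c stands at 0.69, 169 genes away.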

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

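Fits without replicate 2 of both groups, and all alternatives for the neighbourhood of Ptpn9, were chosen after seeing the data. Ptpn9 kept its direction in every alternative, from -0.47 with the lens covariate to -0.69 without replicate 2 of both groups, and did not pass correction in any. The count of clusters past correction was 0 in limma (803 at an unadjusted p under 0.05), 1 with the replicate block (2063), and 0 in every fit that left out an array (636 to 1298). At the unadjusted level, clusters above the median gave 431, the fit of all 35557 clusters 1331, and the fits without knockout replicate 1 and without knockout replicate 2 gave 1298 and 1221. An adjusted p under 0.1 gave 1 cluster, of Unc13c, and an unadjusted p under 0.05 with a 1.5-fold difference gave 15, all higher in the knockout. Several of these 15 were Unc13c clusters, so they stand for fewer genes. The 14 list calls became 0 with an estimated correlation, 0 in directional fry and 0 in mixed fry, 8 among clusters above the median, 5 with the lens covariate (3 of them shared with the 14), and 8 to 17 when arrays were left out in turn. The causes of the lost list calls were not tested. Above the median signal the lens, immune and interferon lists held 3 members each, under the minimum of 5, and were not tested there. With the replicate block 13 of the 14 lists were called, interferon being lost (adjusted p = 0.0742, with a range from 0.00791 to 0.853 over its alternatives). With the block the excess over all 50 genes near Ptpn9 stood, at 22% against 8.47% (Fisher's exact p = 0.00274). At 6 to 25 places alone it was 17.5% against 8.36%, no longer past 0.05 (Fisher's exact p = 0.0764). The block took camera's one-way p for the 50 genes to an unadjusted 0.0348, while the fixed list of 31 neighbours gave a camera p of 0.501. The block also added the Unc13c cluster over all clusters and, over a list alone, Cdh5, Mmrn2, Robo4, C1qa, C1qb, C1qc, Wfdc1, Ptprb, Hif3a and Per1. Beside these and interferon it changed no other call of a gene or list. With the lens covariate the ganglion list reversed to 0.079, photoreceptors stood at -0.16, hypoxia at -0.055 and immune genes at -0.0079, and with arrays left out in turn photoreceptors ranged from -0.092 to 0.082, hypoxia genes from -0.0033 to 0.15, immune genes from 0.059 to 0.17, stress response genes from -0.070 to -0.014, ganglion cell genes from -0.089 to 0.0050 and Xist with Y-linked genes from -0.31 to 0.22, and the cause was not tested. The lens list was not refitted with its own mean as covariate. For vascular genes the adjusted p ranged from 9.23e-14 to 0.604. Near Ptpn9 the share was 8% with the lens covariate (Fisher's exact p = 0.108) and 8% without replicate 2 of both groups (p = 0.0669), and 6 to 12% when arrays were left out, against 16%, and the cause was not tested. Arrays hold no counts, so dim transcripts carry signal near background and their differences are compressed.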

Other observations

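The tests of a linked segment, of an effect on adjacent genes, of carried-over tissue and of RNA from both sexes were chosen after the results were seen, as were the genes of the next 2 paragraphs.

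Genes outside the lists were picked for large differences, and those known from endothelium were not tested as a group. Cd34, a surface sialomucin of endothelial and progenitor cells, differed by 0.68 (SE 0.10), Cd93 by 0.61 (SE 0.12), the endothelial adhesion receptor gene Adgrl4 by 0.55 (SE 0.13), the proteoglycan gene Srgn by 0.61 (SE 0.13) and the integrin gene Itga1 by 0.35 (SE 0.064). In each of these genes all knockout arrays lay above all wild-type arrays, and none passed correction (limma, lowest adjusted p = 0.437). Metabolic and growth genes with large differences were the glycogen-targeting subunit gene Ppp1r3c (0.90, SE 0.35), the retinol carrier gene Rbp4 (0.64, SE 0.20) and the growth factor gene Igf2 (0.39, SE 0.091). Without knockout replicate 3 the differences of Ppp1r3c and Rbp4 were 0.41 and 0.39.

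Clock genes differed in sign. Per1 differed by 0.69 (SE 0.34) and Ciart by 0.41 (SE 0.20), while Per3 differed by -0.31 (SE 0.088). The alpha-2-macroglobulin gene A2m differed by 0.46 (SE 0.12), and the metallothionein gene Mt2 by 0.95, with an SE of 0.57 and of 0.16 with the replicate block, higher in the knockout for 3 of 3 replicate numbers. Per1 moved to 1.05 without knockout replicate 1 and to 0.41 without knockout replicate 2, and Ciart to 0.69 and 0.27, the latter also without knockout replicate 3. Mt2 stood at 0.47 without knockout replicate 2, at 1.63 without wild-type replicate 2 and at 0.52 without wild-type replicate 3. Of these genes Per1 passed over its list alone with the replicate block, and none passed without it.

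The excess of low p values near Ptpn9 was strongest beside the gene, at 4 of 10 genes within 5 places and 4 of 40 at 6 to 25 places (Fisher's exact p = 0.0378, and 0.0764 with the replicate block). Local clustering of low p values as a common feature of chromosomes is argued against. Only 0.227% of 50-gene windows in the genome held as many as the 50 neighbours, with Ptpn9 itself left out (0.138% of 51-gene windows with Ptpn9 counted, as first run). Windows over the Ptpn9 region were among those counted, and clustering particular to that region was not tested. A linked chromosome segment of another origin may reach farther, and genes 26 to 250 places away had a share of 5.33% against 3.17% on other autosomes (odds ratio 1.72, Fisher's exact p = 0.0147), but the unlinked X chromosome had 6.33%. With the replicate block the shares were 9.78%, 8.36% and 10.6% (Fisher's exact p = 0.301 for the first 2). That segment and an effect of the allele on adjacent genes alone therefore cannot be told apart. Unc13c, Mns1 and Adpgk all lie on chromosome 9, at most 169 genes from Ptpn9, and whether they follow the Meg2 protein or the segment was not tested.

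The higher endothelial and pericyte list in the knockout may reflect more vessels in the tissue, more surrounding tissue carried over at dissection, or more blood. With the lens score as a covariate the list's mean was 0.048 in place of 0.15, under the between-array SD of 0.083, but the lens score itself differed between genotypes by 0.13, so carry-over and genotype cannot be told apart. Only 3 of 25 lens members and 6 of 27 vascular members lay above the median signal, and 0 genes of either list stood in another list. The 8 globin clusters averaged 0.15 higher in the knockout with an SE of 0.25, so more blood stays open too. That rise lay in the clusters shared by several globin genes, at 0.24 to 0.38, and the others lay between -0.084 and 0.050. The red blood cell list went the other way, with a mean of -0.024 (camera, adjusted p = 0.227). A biological effect of Meg2 loss on vessels stays open and was not tested separately.

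Both replicate 2 arrays carried Xist and Y-linked signal together. Xist read 12.54 in both replicate 2 samples, near the replicate 1 arrays (12.58 and 12.73) and far above the replicate 3 arrays (6.26 and 6.52). Eif2s3y, Kdm5d and Uty were nonetheless higher on replicate 2 than on replicate 1 in both genotypes, by 0.625 to 2.97, each beyond at least 99.53% of clusters of like signal, while Usp9y, Zfy1 and Zfy2 were left out because they were not raised on replicate 3 either. Raised signal of dim clusters in general is argued against, since clusters of like signal had median differences of at most 0.127 in size. The values are consistent with RNA of both sexes in these samples, with Y-linked signal above replicate 1 at 12.4% to 28.6% of that on replicate 3, although the labels describe 1 animal per sample, and no biological explanation was tested.

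The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. All 10 of the splits gave 0 clusters past correction. The real split gave 14 lists, as 1 of the 10, and the highest other gave 13. It gave 16% near Ptpn9, again as 1 of the 10, and the highest other gave 8%. For the endothelial and pericyte list the real split was not the highest, with a mean difference of 0.1535 in size against 0.1695 in another split. Splits that part all 3 replicate pairs are the closer comparison. They are too few for a test, and any genotype difference adds to the residual spread of the others, which can lower their counts. At an unadjusted p under 0.05 they gave 803 clusters for the real one and 285, 333 and 355 for the others. In the same order those others gave 1, 10 and 3 lists, and 2%, 0% and 2% near Ptpn9. Their endothelial and pericyte means differed by 0.0059, 0.11 and 0.047 in size. Splits that kept a pair together gave up to 2232 clusters at that unadjusted level, which points to the structure shared by replicate numbers.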
